A study of Mus musculus with 9 samples.

How the data were processed

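Total RNA from confluent glial cultures of nontransgenic, SOD1-G93A and SOD1-WT mouse pups (3 biological replicates each, 9 arrays, per the series design text) was amplified by 1 round of T7 transcription with the Illumina TotalPrep kit, labelled with biotin and read on an Illumina mouse BeadArray. The labels do not say whether replicates came from separate litters, give no sex of the pups and place all 3 lines on a mixed B6SJL background. Per the submitters' processing notes the arrays were processed in BeadStudio, whose version is not stated.

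The deposited raw table gives, per the file headers, a mean bead intensity, a bead count, a standard error of bead intensities and a detection p-value for each of 24613 probes on each array. From the values, the intensities were neither background-subtracted nor scaled between arrays. A second deposited table by the authors holds normalised intensities: each array's values were a straight line of its raw intensities (largest residual 0.00905), with a background taken off and all arrays brought to the same mean of 204.3. Between 21.8% and 23.4% of its values were below 0, so it was used as an alternative only, after 11.1 had been added to each value before taking log2.

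Raw intensities were corrected and normalised with neqc in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the package data.table), which fits background from negative controls, here inferred from the detection p-values, adds an offset of 16, scales by quantiles and takes log2. Probes with a detection p below 0.01 on at least 3 of the 9 arrays were kept, 13972 in all. Of the 24613 probes, 20984 were paired with 1 symbol, 1 with several and 3628 with none in the annotation of the platform. Of the kept probes 12284 had 1 symbol, for 9842 genes. Symbols were matched to a mouse gene table for assembly GRCm38.p6 by gene identifier (20968 probes) or accession (8), 9 were kept as given, and 7 were updated. That table served only for names and for which genes neighbour each other, since the files name no genome build. Mean bead counts per probe were 34.8 to 35.7 per array.

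All 9 arrays entered 1 limma fit with 3 groups and no intercept (6 residual and 7.52 prior degrees of freedom). The moderated test was two-sided with Benjamini-Hochberg adjustment over kept probes within each comparison and a threshold of 0.05. The comparisons were SOD1-G93A against nontransgenic, SOD1-G93A against SOD1-WT, SOD1-WT against nontransgenic and SOD1-G93A against the mean of both controls, with a count of probes changed the same way against both. Values are log2 changes with standard errors unless given as SD.

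Before the data were examined, the groups, tests, alternatives, named-gene rule and 26 gene lists were fixed. The lists were astrocyte, microglia and macrophage, oligodendrocyte lineage, neuron, endothelial, ependymal and choroid plexus, fibroblast and meninges, erythroid, sex-linked, forebrain identity, hindbrain and spinal identity, secreted factors and receptor linked to SOD1-G93A glia by the study, cytokines and chemokines, prostaglandin pathway, interferon response, complement and MHC class I, reactive astrocyte, trophic factors, oxidative stress and NRF2, unfolded protein and heat shock, lysosome and cathepsins, oxidative phosphorylation, cholesterol synthesis, glutamate and potassium handling, extracellular matrix and TGF-beta targets, and cell cycle. The 24 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. A gene stood for its list by its kept probe with the highest mean. Of the 6 genes in the study's list all stand in others too: Ccl8, Ccl5 and Ppbp among cytokines and chemokines, Ptgdr in the prostaglandin pathway, and Gmfb and Shh among trophic factors. Shifts of those lists in mutant glia are therefore not fully independent of the study's choice, and no run left these genes out. Igf2 is in the meningeal and trophic lists, Slc1a2, Slc1a3 and Glul in the astrocyte and glutamate lists, and Slc7a11 in the NRF2 and glutamate lists.

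Named genes were, per comparison, the 10 largest rises and 10 largest falls among probes past the threshold whose groups do not overlap, up to 4 members of each list with the smallest p, and Sod1, Gfap and the 6 genes of the study's list. Probes without a symbol, or with a symbol that is only a clone or predicted gene, were counted but not named.

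The fit was tested on simulated data in which 200 of the 13972 probes were shifted: a log2 shift of 1 was recovered for 99.5% to 100% of probes in each comparison and a shift of 0.5 for 51.5% to 85.5%, with 0 calls of the wrong sign. With shifts of 0.5 to 2, between 5 and 18 unshifted probes were called in each comparison. With 1 of the 24 lists shifted by 0.5, 1 other list was called in each comparison but SOD1-WT against nontransgenic (0). For comparisons that share a group, 100 data sets without any changed probe were simulated. Alternatives, changed 1 at a time, were no background correction, an offset of 50, median scaling, cyclic loess, the authors' normalised values, no filter, detection on all 9 arrays, pairwise fits, a variance trend with robust priors, array weights, the replicate number as a block, the mean of all probes of a gene, and each array left out in turn. A block for the slide was not run, since the files used here give no slide. Figures were drawn with matplotlib 3.10.9 from Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.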

Results

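Messenger RNA was profiled on 9 Illumina mouse arrays from primary glia, the non-neuronal cells of nervous tissue, which in such cultures are usually for the most part astrocytes. The tissue of newborn pups had been stripped of its meninges, per the labels, and the cells were grown to confluence. The cultures came from 3 kinds of pups, with 3 biological replicates of each. Nontransgenic pups carried no transgene. SOD1-G93A pups carried human superoxide dismutase 1 with a mutation that causes amyotrophic lateral sclerosis, and SOD1-WT pups carried the normal human protein. The 9 arrays detected between 13107 and 13618 probes each, 53.3% to 55.3% of the 24613 on the array. The mean signal was 211 to 236 units on 8 arrays and 279.6 on SOD1-WT replicate 3, where the bead standard error was also larger, at a median of 8.34% of the signal against 4.74% to 4.98% elsewhere. Arrays of 1 group correlated at 0.988 to 0.995, against 0.954 to 0.968 between nontransgenic and SOD1-WT glia. The number of arrays limits the precision of every value, and whether the spread between replicates includes that between litters is not stated.

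**Figure D1:**
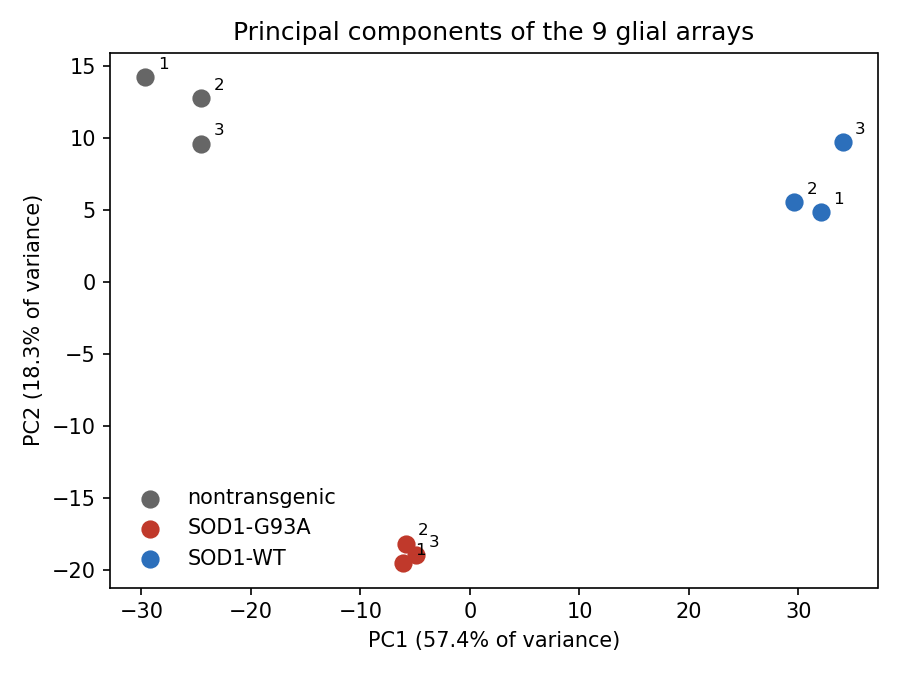
Scores of the 9 arrays on the first and second principal components of normalised log2 intensity over the kept probes, with the percent of variance on each axis and a colour per group. On the first component the nontransgenic arrays lie from -29.6 to -24.5, the SOD1-G93A arrays from -6.11 to -4.93 and the SOD1-WT arrays from 29.6 to 34.0.

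The 3 groups lay apart on the first principal component, which held 57.4% of the variance, with the mutant glia between the control groups. Of the 3539 probes that differed between SOD1-WT and nontransgenic glia, 2804 (79.2%) had a SOD1-G93A mean between both. A mean that matches 1 control but for noise can fall between too. Of the 3539, SOD1-G93A differed past the threshold from both controls at 462 probes and from neither at 1280. Endogenous Sod1, the mouse superoxide dismutase gene, was measured as a check on the transgenes. Both are human, so a mouse probe may not detect them. Its mean log2 intensity was 10.94 ± 0.18 in nontransgenic, 11.11 ± 0.09 in SOD1-G93A and 11.27 ± 0.04 in SOD1-WT glia (SD, n = 3). The change was 0.17 ± 0.11 (SE) for SOD1-G93A against nontransgenic (limma adjusted p = 0.396), -0.16 against SOD1-WT (adjusted p = 0.385) and 0.33 ± 0.11 for SOD1-WT against nontransgenic (adjusted p = 0.0338). This last call ended without nontransgenic replicate 2 (0.27, adjusted p = 0.139) or 3 (0.29, 0.109) and without SOD1-WT replicate 1 (0.35, 0.0615), 2 (0.34, 0.0658) or 3 (0.31, 0.0663). It also ended in other settings given in the closing section, and the adjusted p over all alternatives ranged from 0.0097 to 0.2.

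Mutant glia were compared with nontransgenic glia to find candidate genes of the toxicity of SOD1-G93A glia, the aim in the series title, and had more of several chemokine transcripts. Ccl2, which draws monocytes, was 5.58-fold higher in SOD1-G93A glia (log2 change 2.48 ± 0.15 SE, limma adjusted p = 1.2e-07, n = 3 per group). Ccl12, a related monocyte chemokine, was at least 35.7-fold higher by 1 of its probes (adjusted p = 1.09e-12), while its other kept probe gave -0.36 (adjusted p = 0.142). Sparc, a matrix-binding glycoprotein that astrocytes secrete, rose by 2.99 ± 0.16 (adjusted p = 4.86e-08), and Gfap, the intermediate filament of astrocytes, rose 1.69-fold (0.76 ± 0.15, adjusted p = 0.00441). Taldo1, an enzyme of the pentose phosphate pathway, fell by 2.36 ± 0.11 (adjusted p = 7.03e-09), and Thsd4, a fibrillin-binding matrix protein, fell by 2.84 ± 0.10 (adjusted p = 2.29e-10). In each of these changes every array of the higher group lay above every array of the other, which the naming rule required of all but Gfap. In SOD1-WT glia the mean of each of these genes (Ccl12 by the same probe) differed from nontransgenic glia in the same direction. These changes are thus not particular to the mutant in direction. Mean log2 intensities in nontransgenic, SOD1-G93A and SOD1-WT glia were 5.69, 8.18 and 7.20 for Ccl2 and 7.88, 10.87 and 11.38 for Sparc. They were 8.71, 9.47 and 9.69 for Gfap, 10.75, 8.38 and 9.20 for Taldo1, and 9.95, 7.11 and 5.89 for Thsd4.

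At an adjusted p of 0.05, 1487 of the 13972 kept probes differed, 714 higher and 773 lower in SOD1-G93A glia, and 203 of them by 2-fold or more. Where a gene was below background on every array of its dimmer group, its fold between 2 groups is given as a lower bound, with the dim group set to the dimmest detected probe of each of its arrays. Where a fitted log2 value is given for such a gene, as against the mean of both controls, it depends on the offset and is no bound. The other large rises were Pttg1, the securin that restrains chromatid separation (at least 10.6-fold), Tmem68 (at least 10.5-fold), Plek, a protein kinase C substrate of blood cells (at least 5.88-fold), and Coq2, an enzyme of coenzyme Q synthesis (at least 5.10-fold). They were followed by Parp12, an interferon-induced ADP-ribosyltransferase (log2 change 2.54, detected on 2 of 3 nontransgenic arrays), and Glycam1, a mucin-like ligand of selectin (2.33). Ttr, the thyroxine carrier made by choroid plexus, rose by 2.93 ± 0.52 (adjusted p = 0.00206) with a wide spread in the mutant group (SD 1.63). Its call ended with a variance trend and robust priors (adjusted p = 0.057, range over alternatives 4.68e-07 to 0.057). Among the large falls were Pdrg1, a p53-regulated gene (at least 20.05-fold), and the nonclassical MHC class I genes H2-T23 (log2 change -4.17, detected on 1 of 3 mutant arrays) and H2-T22 (-2.26, and -0.54 by its other probe). Abhd16a, a phospholipid lipase, fell by 4.04 (detected on 1 of 3 mutant arrays). Others were Reg3g, an antibacterial lectin (at least 8.54-fold), Entpd3, an ectonucleotidase (-3.10, detected on 2 of 3 mutant arrays), Ext2, a heparan sulfate polymerase (-2.33), and Zfp960, a zinc finger gene (at least 4.08-fold). Mean log2 intensities of Reg3g, Entpd3 and Ext2 were low in SOD1-WT glia too (4.30, 4.24 and 4.56). Those of Pdrg1, H2-T23, H2-T22, Abhd16a and Zfp960 were not (8.06, 9.03, 8.64, 9.79 and 6.47).

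The 5 factors and 1 receptor that the study linked to mutant glia were fixed as a list before the data were examined, and all 6 measured genes were higher in SOD1-G93A than in nontransgenic glia. This list is not independent evidence, since the study chose it on these samples. The receptor Ptgdr, which binds prostaglandin D, was detected on the 3 mutant arrays and on none of the 6 others, at least 1.56-fold higher (limma adjusted p = 6.6e-06). The chemokine Ccl8 was 2.24-fold higher (log2 change 1.16 ± 0.19, adjusted p = 0.000888), Ccl5, a T cell attractant, 1.96-fold (0.97 ± 0.14, adjusted p = 0.000473), and Ppbp, a platelet chemokine, 2.16-fold (1.11 ± 0.20, adjusted p = 0.0024). Gmfb, a glia maturation factor, was at least 1.33-fold higher (adjusted p = 0.00304), and Shh, the hedgehog morphogen, 1.92-fold (0.94 ± 0.11, adjusted p = 7.8e-05). All 6 also rose adjusted over the list alone, and the median log2 change was 0.98, or 0.96 with the dim genes at their bound (camera adjusted p = 6.22e-08; adjusted p = 0.0786 with an estimated correlation).

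**Figure D2:**
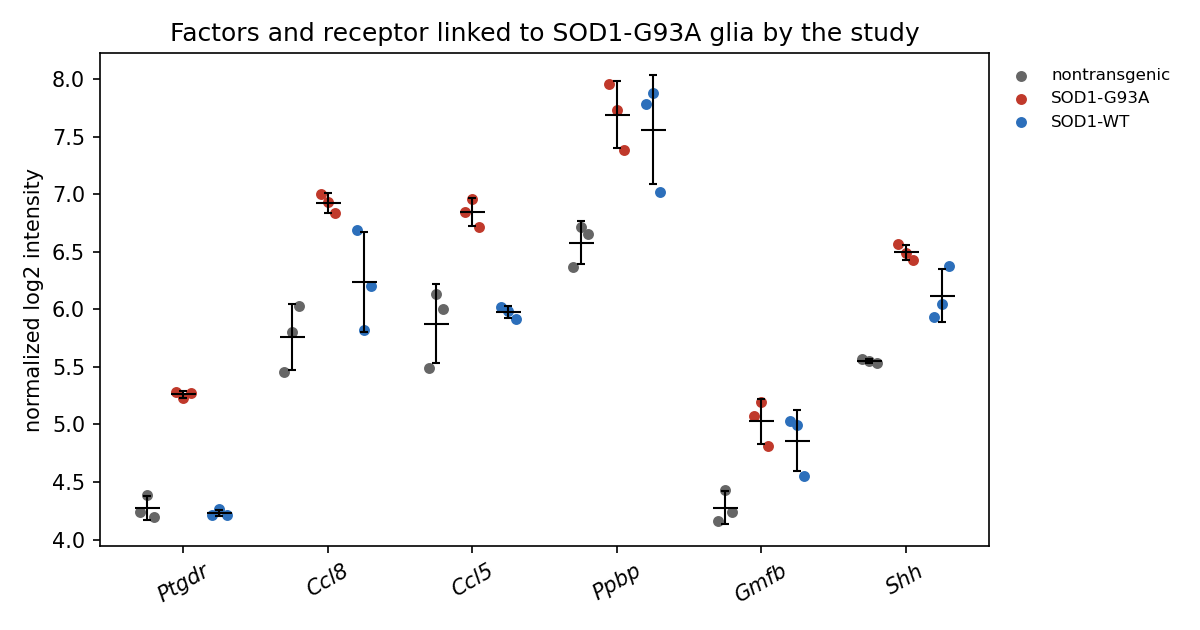
Normalised log2 intensity of Ptgdr, Ccl8, Ccl5, Ppbp, Gmfb and Shh on each array by group, with points for arrays and bars for the mean ± SD (n = 3). Ptgdr has means of 4.27, 5.26 and 4.23 in nontransgenic, SOD1-G93A and SOD1-WT glia, while Ppbp has 6.58, 7.69 and 7.56.

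Of the other gene lists, 4 shifted in SOD1-G93A against nontransgenic glia, and none of these calls held with an estimated correlation between genes. The list of cytokines and chemokines rose, with 7 of 24 genes higher, 1 lower and 16 not past the threshold, the same counts adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.230 with an estimated correlation). Beside Ccl2 and Ccl5 it holds Cxcl10, an interferon-induced chemokine (at least 2.91-fold higher), and Il33, an alarmin, which fell by 0.81. Ccl12 stands in it by its brighter probe, which gave -0.36. Because 3 of its genes also stand in the study's list, its rise is not fully independent evidence. The cell cycle list was lower, with 0 genes higher, 6 lower and 13 not past (0 and 9 adjusted over the list alone; camera adjusted p = 0.000338; adjusted p = 0.264 with an estimated correlation). Its lower genes include the spindle checkpoint kinase Bub1b (-0.62, detected on 1 of 3 mutant arrays) and the survivin gene Birc5 (-0.45, and -0.28 and -0.38 by its other probes, which did not pass). The Birc5 call ended without nontransgenic replicate 2 (-0.41, adjusted p = 0.0727) or SOD1-G93A replicate 2 (-0.43, adjusted p = 0.0644), with a range over alternatives of 0.00204 to 0.0727. The Bub1b call ended without nontransgenic replicate 2 (-0.58, adjusted p = 0.0725) or 3 (-0.49, 0.0782) and without SOD1-G93A replicate 1 (-0.60, 0.0647) or 2 (-0.53, 0.0838), with a range of 0.0024 to 0.0838. The list of hindbrain and spinal identity was higher, with 2 of 6 genes up, 0 down and 4 not past (4 and 0 adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.197 with an estimated correlation). These were the homeobox genes En2, active at the border of midbrain and hindbrain (at least 2.0-fold), and Irx3 (log2 change 0.58). The list's call also ended with no filter (adjusted p = 0.181, range over alternatives 0.000245 to 0.197).

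The list of ependymal and choroid plexus markers was higher as well, with 4 of 7 genes up, 2 down and 1 not past, the same adjusted over the list alone (median log2 change 0.76; camera adjusted p = 0.049; adjusted p = 0.230 with an estimated correlation). Higher were Otx2, a choroid plexus transcription factor (1.63), Folr1, a folate receptor (1.44), and Dynlrb2, a dynein chain (0.76), while the water channel Aqp1 fell by 1.88, and by 1.27 by its other probe. This call held in 12 of 23 alternatives, with adjusted p from 0.000786 to 0.230, and ended without nontransgenic replicate 1 (0.0876) or 3 (0.11), SOD1-G93A replicate 1 (0.0586) or SOD1-WT replicate 2 (0.0573) or 3 (0.0507). The cytokines and chemokines call ended without SOD1-G93A replicate 1 (adjusted p = 0.054, range over alternatives 0.00149 to 0.230), where 3 lists shifted in place of 5, and with probes detected on all arrays (0.0728). Markers of fibroblasts and meninges were not shifted in this comparison (3 of 13 higher, 4 lower, median -0.05, camera adjusted p = 0.844).

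Glia with mutant SOD1 were next compared with glia carrying normal human SOD1, to ask what the mutation adds to carrying a transgene. The mutation cannot be singled out here, since a Y-linked signal set the SOD1-WT arrays apart, as given further below. Transcripts typical of the meninges, the connective tissue sheets around the brain, were far higher in SOD1-G93A glia. Ptgds, the prostaglandin D synthase abundant in the leptomeninges, was 65.9-fold higher (log2 change 6.04 ± 0.09 SE, limma adjusted p = 2.03e-14, n = 3 per group). Mgp, a matrix protein that blocks calcification, rose by 4.43 ± 0.14, and Lum, a proteoglycan of collagen fibrils, by 3.71 ± 0.10 (detected on 1 of 3 SOD1-WT arrays). Means of Ptgds were 13.16 in nontransgenic, 12.90 in SOD1-G93A and 6.86 in SOD1-WT glia.

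In this comparison 2102 probes differed, 966 higher and 1136 lower in SOD1-G93A glia, and 374 by 2-fold or more. Further large rises were Fam180a (at least 14.17-fold), Vtn, the adhesion protein vitronectin (log2 change 3.40), Vsig4, a complement receptor of tissue macrophages (3.38), and Cdh5, the cadherin of endothelial junctions (at least 8.49-fold). Others were Lyve1, a hyaluronan receptor of lymphatic endothelium and macrophages (3.10), Ranbp3l (3.21, detected on 2 of 3 SOD1-WT arrays), and Foxc2, a mesenchymal transcription factor (at least 6.79-fold). Large falls were Abhd16a (-5.03) and H2-T23 (-4.53), both detected on 1 of 3 mutant arrays, Pdrg1 (at least 10.86-fold), Plac9a (at least 8.53-fold) and H2-T22 (-2.82, but -0.70 by its other probe). They were followed by Odf3b (-2.54, and -2.83 by its other probe), the Y-linked demethylase Kdm5d (at least 5.03-fold), the meiotic cohesin Rec8 (at least 4.85-fold), the complex I subunit Ndufb10 (-2.39), and the protease Ctsc (-3.02, but -0.23 by its other probe, adjusted p = 0.249).

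Of the study's 6 genes, 4 rose against SOD1-WT, and 4 adjusted over the list alone, which is again not independent evidence. The list was higher (median log2 change 0.53, or 0.52 with the dim gene at its bound; camera adjusted p = 0.00289; adjusted p = 0.122 with an estimated correlation). Ptgdr was at least 1.58-fold higher (adjusted p = 2.33e-06) and Ccl5 rose by 0.87 (adjusted p = 0.000708). Ppbp gave 0.13 (adjusted p = 0.756) and Gmfb 0.17 (adjusted p = 0.509). Ccl8 rose by 0.69 (adjusted p = 0.0221, range over alternatives 0.00223 to 0.117), a call that ended without SOD1-G93A replicate 1 (0.65, 0.0828) or 2 (0.69, 0.0638) or SOD1-WT replicate 2 (0.48, 0.0926). Shh rose by 0.38 (adjusted p = 0.0395, range 0.00284 to 0.148), and its call ended in 11 of 20 alternatives. Among these were the fits without nontransgenic replicate 2 (0.38, 0.0578) or 3 (0.38, 0.0521), SOD1-G93A replicate 1 (0.34, 0.139), 2 (0.38, 0.0955) or 3 (0.41, 0.0683), and SOD1-WT replicate 1 (0.29, 0.148) or 2 (0.34, 0.118). The call of the list, the secreted factors and receptor linked to SOD1-G93A glia by the study, ended without SOD1-G93A replicate 1 (adjusted p = 0.0865) or 2 (0.0707), with a range of 0.00078 to 0.122. Gfap did not differ past the threshold (-0.22, adjusted p = 0.401).

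The list of fibroblast and meninges markers was higher in SOD1-G93A than in SOD1-WT glia, with 11 of 13 genes up, 0 down and 2 not past, the same adjusted over the list alone (median log2 change 1.23; camera adjusted p = 1.04e-14; adjusted p = 0.0227 with an estimated correlation). Its largest rises were Lum, the fibrillar collagens Col1a1 (2.32) and Col1a2 (1.89, detected on 1 of 3 SOD1-WT arrays) and the GABA transporter Slc6a13 (2.26). Another 5 lists rose beside this shift of the meningeal markers, each losing its call with an estimated correlation. In the prostaglandin pathway 8 of 15 genes were higher, 0 lower and 7 not past (8 and 1 adjusted over the list alone; camera adjusted p = 3.3e-05; adjusted p = 0.0652 with an estimated correlation). These include Ptgds, Ptgis, the prostacyclin synthase (at least 3.36-fold), the receptor Ptger3 (at least 1.47-fold) and Ptgdr. In the list of extracellular matrix and TGF-beta targets 10 of 19 were higher, 1 lower and 8 not past (11 and 2 adjusted over the list alone; camera adjusted p = 0.000603; adjusted p = 0.061 with an estimated correlation). The gelatinase Mmp2 rose by 1.47, stromelysin Mmp3 by 1.27 and fibronectin Fn1 by 1.14, while the 3 other probes of Fn1 gave 0.06, 0.75 and 1.25.

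Cytokines and chemokines had 11 of 24 genes higher, 1 lower and 12 not past (12 and 1 adjusted over the list alone; camera adjusted p = 0.00103; adjusted p = 0.0652 with an estimated correlation). Cxcl12, which meningeal cells also make, rose by 1.68, Ccl6 by 1.12 and Ccl2 by 0.98. Ccl5, Ccl8 and Ppbp of this list also stand in the study's list, as do Gmfb and Shh of the trophic factors. Neither list is thus fully independent evidence. Trophic factors had 8 of 20 higher, 1 lower and 11 not past (8 and 1 adjusted over the list alone; camera adjusted p = 0.00289; adjusted p = 0.0652 with an estimated correlation). Bmp4, a bone morphogenetic protein, rose by 1.69 and Igf2, a growth factor that also stands in the meningeal list, by 1.23. The oligodendrocyte lineage list had 3 of 13 higher, 0 lower and 10 not past (4 and 1 adjusted over the list alone; camera adjusted p = 0.0111; adjusted p = 0.122 with an estimated correlation). Of those 3, Cldn11, a tight junction protein (2.44), and Pdgfra, a growth factor receptor (1.49), are also made by meningeal cells and fibroblasts, while Sox10 (0.80) is a transcription factor of the lineage. The prostaglandin pathway call ended when only probes detected on all arrays were kept (adjusted p = 0.0571, range over alternatives 4.86e-06 to 0.0652).

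The comparison of SOD1-WT with nontransgenic glia was meant to ask what the normal human protein does by itself, and it had the highest count of changed probes. It cannot isolate the protein, since the Y-linked Kdm5d was detected on all 3 SOD1-WT arrays and on no other. SOD1-WT glia had far less of the meningeal transcripts than nontransgenic glia: Ptgds was 78.9-fold lower (log2 change -6.30 ± 0.09 SE, limma adjusted p = 1.15e-14, n = 3 per group) and Mgp 68.1-fold lower (-6.09 ± 0.14). Sparc rose by 3.50 ± 0.16 (adjusted p = 2.52e-09) and Gfap by 0.98 (adjusted p = 0.00023). Past the threshold were 3539 probes, 1888 higher and 1651 lower in SOD1-WT glia, and 653 by 2-fold or more. Without SOD1-WT replicate 3, the array with the larger bead error, 3465 probes passed here, 1885 in SOD1-G93A against SOD1-WT and 1859 in SOD1-G93A against nontransgenic glia.

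Among the genes with large rises were several that also rose in the mutant: Ccl12 (at least 24.4-fold, while its other probe fell by 0.82, adjusted p = 0.000628), Pttg1 (at least 20.96-fold), Tmem68 (at least 11.7-fold), Plek (at least 8.96-fold) and Coq2 (at least 6.57-fold). Ctsc (at least 8.86-fold, but 0.82 on the log2 scale by its other probe), Plac9a (log2 change 2.85, and 2.62 by its other probe) and Kdm5d (at least 5.05-fold) followed. Kif3a, a kinesin of ciliary transport, rose by 2.80, and by 1.31 by its other probe. Large falls were Fam180a (at least 23.03-fold), Foxc2 (at least 21.06-fold), Cdh5 (at least 16.6-fold), the growth factor binding protein Igfbp6 (-4.71), Ranbp3l (-4.47, detected on 2 of 3 SOD1-WT arrays), Aqp1 (-4.45, and -2.02 by its other probe), the retinol transporter Stra6 (-4.19) and Vtn (-4.13). Of the study's 6 genes, 3 rose, and 4, with Ccl8, adjusted over the list alone (median log2 change 0.52, or 0.36 with the dim genes at their bound; camera adjusted p = 0.0854). The 3 were Ppbp (0.98, adjusted p = 0.00239), Gmfb (at least 1.18-fold, adjusted p = 0.00729) and Shh (0.57, adjusted p = 0.00199). Ccl5 gave 0.10 (adjusted p = 0.679) and Ptgdr, below background in both groups, -0.04 (adjusted p = 0.791). Ccl8 gave 0.47 (adjusted p = 0.0804) and passed without nontransgenic replicate 3 (adjusted p = 0.0477) or SOD1-WT replicate 2 (0.012).

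Markers of fibroblasts and meninges were lower as a list in SOD1-WT than in nontransgenic glia, with 11 of 13 genes down, 0 up and 2 not past, the same adjusted over the list alone (median log2 change -1.56; camera adjusted p = 2.92e-11; adjusted p = 0.0457 with an estimated correlation). Among its falls were Fbln1, a basement membrane protein (-3.03), Lum (-2.92, detected on 1 of 3 SOD1-WT arrays), Col1a1 (-2.91) and Slc6a13 (-2.10). Beside this shift, the list of extracellular matrix and TGF-beta targets was lower, with 2 of 19 up, 10 down and 7 not past, the same adjusted over the list alone (camera adjusted p = 0.00845; adjusted p = 0.124 with an estimated correlation). Its lower genes include Mmp2 (-1.57), the collagen crosslinking enzyme Lox (-1.45) and the thrombospondin Thbs2 (-1.10), while Sparc rose. In the prostaglandin pathway 1 of 15 genes was higher, 5 lower and 9 not past (2 and 5 adjusted over the list alone; camera adjusted p = 0.00935; adjusted p = 0.252 with an estimated correlation). The lower genes include Ptgds, Ptgis (at least 10.8-fold lower), Ptges, a prostaglandin E synthase (-1.36, detected on 1 of 3 SOD1-WT arrays), and Ptger3 (at least 1.96-fold lower). Among trophic factors 2 of 20 were higher, 7 lower and 11 not past (2 and 9 adjusted over the list alone; camera adjusted p = 0.0414; adjusted p = 0.206 with an estimated correlation). Among the falls were Bmp4 (-2.27), Igf2 (-1.63) and Tgfb1, a transforming growth factor (-0.93). The trophic factors call ended without nontransgenic replicate 2 (adjusted p = 0.0582) and with the deposited normalised values (0.0596), in a range of 3.83e-05 to 0.206. The prostaglandin pathway call ended with probes detected on all arrays (0.218, range 5.62e-06 to 0.252). Without SOD1-WT replicate 3, 7 lists shifted in place of 4, with cell cycle, hindbrain and spinal identity and the study's list added, each at an adjusted p of 0.0373. The cell cycle list also passed without nontransgenic replicate 1 (0.0319) and that of hindbrain and spinal identity without SOD1-WT replicate 1 (0.0406).

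**Figure D3:**
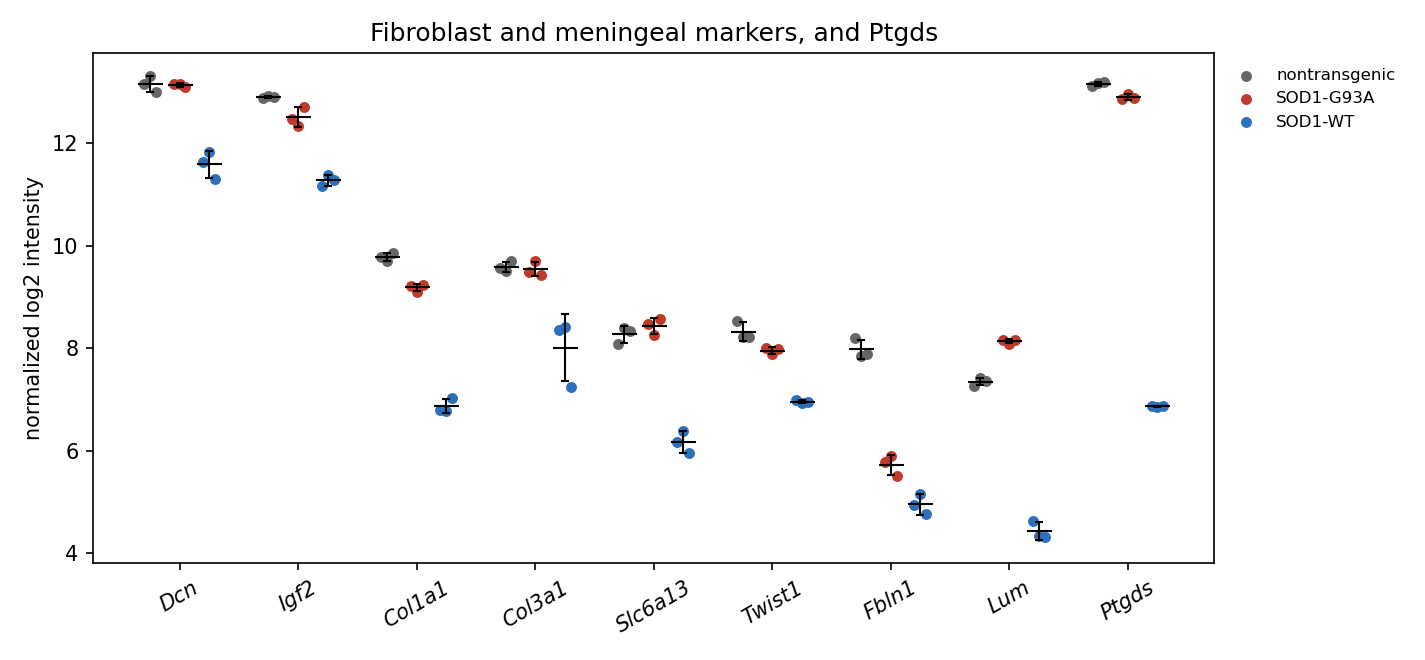
Normalised log2 intensity of 9 meningeal and fibroblast transcripts on each array by group, with points for arrays and bars for the mean ± SD (n = 3). The SOD1-WT arrays are lowest for Ptgds, at a mean of 6.86 against 13.16 in nontransgenic and 12.90 in SOD1-G93A glia.

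A last question was how mutant glia differed from the mean of both control groups, a contrast that a gene lying between the controls can also pass. Chemokines were again higher: Ccl2 in SOD1-G93A glia exceeded the mean of the controls by 1.73 ± 0.13 on the log2 scale (limma adjusted p = 1.23e-06), Ccl6 by 0.93 and Ccl5 by 0.92 (adjusted p = 0.000284). Parp12 was higher by 2.50 ± 0.09 (adjusted p = 8.83e-10), Ada, the adenosine-degrading deaminase, by 1.57, Rab6b, a Golgi trafficking GTPase, by 1.74 ± 0.15, and Ttr by 2.89 ± 0.45 (adjusted p = 0.000969). H2-T23 (-4.35), H2-T22 (-2.54, but -0.62 by its other probe), Abhd16a (-4.53), Pdrg1 (-4.11) and Ndufb10 (-2.08) were lower, where Pdrg1 was below background on all mutant arrays and H2-T23 and Abhd16a on 2 of 3. Other large differences were Lum (2.25), Col1a2 (1.38), Rusc2 (1.61), the neural crest factor Tfap2b (1.50, but 0.80 by its other probe), Tfb1m (-1.81), the initiation factor gene Eif3j1 (-2.24), Zfp960 (-2.37), Plac9a (-2.19) and the guanylate cyclase activator Guca1a (-1.89). Eif3j1 and Zfp960 were below background on all mutant arrays. Ccl12 came to 2.95 by 1 probe and 0.05 by its other.

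Past the threshold in this contrast were 1083 probes, 502 higher and 581 lower, and 299 probes passed in the same direction against each control separately, 156 higher and 143 lower. Without SOD1-G93A replicate 1 these counts were 645 and 188, and without SOD1-G93A replicate 3 they were 693 and 189. All 6 genes of the study's list, not independent evidence, were higher than the mean of the controls, also adjusted over the list alone (camera adjusted p = 2.76e-08; adjusted p = 0.032 with an estimated correlation). Ptgdr rose by 1.01 (adjusted p = 1.96e-06), Ccl8 by 0.93 (adjusted p = 0.00218) and Shh by 0.66 (adjusted p = 0.000657). Ppbp rose by 0.62 (adjusted p = 0.046, range over alternatives 0.0193 to 0.251), but not without nontransgenic replicate 1 (0.57, 0.0921), 2 (0.65, 0.0638) or 3 (0.64, 0.0642) or SOD1-G93A replicate 1 (0.49, 0.251) or 2 (0.60, 0.156). Gmfb rose by 0.46 (adjusted p = 0.0343, range 0.0102 to 0.189), but not without nontransgenic replicate 1 (0.43, 0.0698) or 3 (0.45, 0.0632) or SOD1-G93A replicate 1 (0.44, 0.149) or 2 (0.38, 0.189). Gfap (0.27, adjusted p = 0.295) and Sod1 (0.01, adjusted p = 0.985) did not differ past the threshold.

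Cytokines and chemokines as a list were higher in mutant glia than the mean of the controls, with 12 of 24 genes up, 1 down and 11 not past (13 and 1 adjusted over the list alone, camera adjusted p = 6.89e-06, adjusted p = 0.032 with an estimated correlation). Among its genes, Ccl5, Ccl8 and Ppbp also stand in the study's list, so its shift is not fully independent evidence. The same holds for Gmfb and Shh among the trophic factors and Ptgdr in the prostaglandin pathway. Fibroblast and meninges markers were also higher, with 8 of 13 up, 1 down and 4 not past (10 and 1 adjusted over the list alone; camera adjusted p = 2.65e-09; adjusted p = 0.032 with an estimated correlation). Beside them rose the prostaglandin pathway, with 2 of 15 up, Ptgds (2.89) among them, 0 down and 13 not past (5 and 0 adjusted over the list alone; camera adjusted p = 0.000335; adjusted p = 0.0946 with an estimated correlation). The extracellular matrix and TGF-beta targets rose too, with 4 of 19 up, 1 down and 14 not past (6 and 1 adjusted over the list alone; camera adjusted p = 0.0036; adjusted p = 0.0676 with an estimated correlation). Sparc (1.24) and Mmp2 (0.68) were up and Thbs2 (-0.72) was down. The oligodendrocyte lineage list had 4 of 13 up, 0 down and 9 not past (5 and 1 adjusted over the list alone; camera adjusted p = 0.00801; adjusted p = 0.0946 with an estimated correlation). Sox10 rose by 0.70 and Cldn11 by 0.57. Trophic factors had 5 of 20 up, 1 down and 14 not past (5 and 1 adjusted over the list alone; camera adjusted p = 0.0195; adjusted p = 0.0946 with an estimated correlation). Shh and Bmp4 (0.55) were up and Ptn, the heparin-binding pleiotrophin (-0.62), was down. Of these lists, the last 5 had not shifted against nontransgenic glia alone (camera adjusted p = 0.844 each). There, 3 fibroblast and meninges genes were up and 4 down, 1 and 3 of the prostaglandin pathway, 2 and 3 of the matrix, 2 and 3 of the oligodendrocyte lineage and 2 and 4 of the trophic factors. All 5 had shifted against SOD1-WT, which this contrast averages in. Against nontransgenic glia, Cldn11 (-1.29) and Bmp4 (-0.58) were lower in the mutant, and Ptgds (-0.26, adjusted p = 0.0846) and Mmp2 (-0.10, adjusted p = 0.688) did not differ past the threshold. Sparc was higher than in nontransgenic glia (2.99) but not than in SOD1-WT (-0.50, adjusted p = 0.0557). Cell cycle genes were lower, with 0 of 19 up, 2 down and 17 not past (0 and 2 adjusted over the list alone; camera adjusted p = 0.00302; adjusted p = 0.294 with an estimated correlation). Bub1b fell by 0.67. The cell cycle list did not differ from SOD1-WT alone (0 up, 1 down, median log2 change -0.12, camera adjusted p = 0.425). In SOD1-WT against nontransgenic glia its median was -0.25, against -0.29 in SOD1-G93A (camera adjusted p = 0.0779, past the threshold in 5 of 23 alternatives, range 0.0316 to 0.430). The cell cycle call ended without SOD1-G93A replicate 2 (adjusted p = 0.0529, range 0.000534 to 0.294), and the trophic factors call with probes detected on all arrays (0.131, range 0.00275 to 0.131).

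Comparisons that share a group share its error. SOD1-G93A and SOD1-WT glia changed the same way against nontransgenic glia at 1032 probes. Of these, 476 were higher in both, where independent calls would give 96.5, and 556 lower in both, where they would give 91.3. Another 63 changed in opposite ways, where independent calls would give 188.8. In 100 simulations of unchanged groups that share the controls, the highest same-way count was 1. Without changed probes almost none are called, so this is no chance value for the 1032. Part of the excess of same-way calls may come from the shared controls. The correlation of their changes across probes, which are not independent replicates, was 0.628 against 0.5 simulated, and their covariance 0.0980 against 0.00764 simulated, a difference of 0.0904. For SOD1-G93A against each control in turn, 299 probes changed the same way, 156 higher and 143 lower, where independent calls would give 49.4 and 62.8. Another 376 changed in opposite ways, where independent calls would give 111.5. The highest same-way count simulated was 1, which for the same reason is no chance value for the 299. Part of the excess may come from the shared mutant arrays. The correlation was 0.0142 against 0.501 simulated and the covariance 0.00173 against 0.00766. Of the 299, 86 also differed between the controls.

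Genes that define the main cell types of the culture were compared as lists too, and 14 of the 24 lists tested shifted in no comparison with camera, with a smallest adjusted p of 0.0854. With camera, 2 of them passed under an alternative. These were astrocyte in SOD1-WT against nontransgenic glia with no filter (adjusted p = 0.0386, range over alternatives 0.0124 to 0.430) and cholesterol synthesis in SOD1-G93A against SOD1-WT with the mean of all probes (0.0398, range 0.0157 to 0.339). The astrocyte list came to 0.0972 in SOD1-WT against nontransgenic glia, where 9 of 17 genes were higher and 2 lower. It held rises in Clu, a secreted chaperone (1.02), and Sox9, a glial transcription factor (0.57), and a fall in the gap junction gene Gjb6 (-1.59). Microglia and macrophage markers had a smallest adjusted p of 0.736, in SOD1-G93A against SOD1-WT; against nontransgenic glia the Fc receptor chain Fcer1g rose by 0.99 and Fcgr3 fell by 1.03 in the mutant. Neither the neuron (0.54), endothelial (0.227), forebrain identity (0.364), interferon response (0.235) nor complement and MHC class I list (0.16) passed with camera in any comparison. With fry, the complement and MHC class I list was lower in each comparison (adjusted p from 6.1e-05 to 0.029). The endothelial list passed with fry in each pairwise comparison (1.9e-05 to 0.00491), and forebrain identity in both with SOD1-WT (0.00374 and 0.00716). Reactive astrocyte genes reached 0.2 with camera, with 4 of 21 higher and 6 lower in SOD1-WT against nontransgenic glia (fry adjusted p = 0.0135).

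Stress and metabolic lists were likewise not past the threshold as sets with camera. In SOD1-WT against nontransgenic glia fry called oxidative stress and NRF2 (adjusted p = 0.00241), oxidative phosphorylation (0.00338), cholesterol synthesis (0.00459) and lysosome and cathepsins (0.00917) lower. The same lists passed with fry as higher in SOD1-G93A against SOD1-WT (0.0157 to 0.0492). Oxidative stress and NRF2 genes came to 0.0854 with camera in SOD1-WT against nontransgenic glia, with 2 of 22 higher and 6 lower. Lower were the cystine transporter Slc7a11 (-2.26), the quinone reductase Nqo1 (-1.63) and sulfiredoxin Srxn1 (-0.85), against a rise in the metallothionein Mt2 (0.89). Cholesterol synthesis also came to 0.0854, with 1 of 13 higher and 5 lower. The smallest camera adjusted p was 0.671 for unfolded protein and heat shock, 0.5 for lysosome and cathepsins, 0.2 for oxidative phosphorylation and 0.504 for glutamate and potassium handling. Of the erythroid list 0 of 5 genes were measured, and of the sex-linked list 1 of 5, Kdm5d, so neither was tested. Among the 96 list results, 13 had a median, mean and test that differed in sign, and 0 of these were called.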

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

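The tests of a meningeal share, of an effect of both transgenes and of Y-linked transcripts were chosen after the results were seen, as was the minimum of 5 genes for the test of second probes. A probe outside those kept, for the Y-linked translation factor gene Eif2s3y, was brighter in SOD1-WT than in nontransgenic glia by 0.54 on the log2 scale, a signal in data the comparisons did not use. The bead standard errors, also outside the comparisons, set SOD1-WT replicate 3 apart, with a median of 8.34% of the signal against 4.74% to 4.98% on the other arrays.

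Markers of fibroblasts and meninges had a median log2 change of -1.56 in SOD1-WT against nontransgenic glia, with 84.6% of 13 measured genes called lower. The quality of SOD1-WT replicate 3 is argued against as the cause, since 86.3% of the median remained without it. An effect of carrying either transgene is argued against for the list as a set, since its median in SOD1-G93A glia was 3.51% of that in SOD1-WT glia (-0.05, standard deviation over members 0.79, 3 up and 4 down). It stays open for Fbln1, which fell by 2.26 in SOD1-G93A too, and for Col1a1, Igf2 and Twist1. Those were lower on every SOD1-G93A than on every nontransgenic array, while Lum, Col1a2 and Thy1 were higher. Outside the list it stays open for Mgp (-1.65), Igfbp6 (-1.78), Foxc2 (-1.63) and Stra6 (-1.26). The same holds for Aqp1, Ranbp3l, Cdh5, Vtn and Fam180a. Their means were 9.70, 9.18, 8.65, 9.21 and 9.13 in nontransgenic and 7.83, 7.93, 7.69, 8.48 and 8.43 in SOD1-G93A glia. A smaller share of meningeal cells in the SOD1-WT cultures stays open: it was proposed from the same median of -1.56, which therefore cannot test it, and the called members fell unevenly, from -0.37 to -3.03. An effect of the SOD1-WT transgene or line on these genes stays open too, as untested.

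Several large differences between SOD1-G93A and nontransgenic glia sat on single probes near background in 1 group, as for Pdrg1, H2-T23 and Abhd16a. Of the 31 genes with a log2 change of 2 or more, 2 pairs lay within 10 measured genes of each other, Ccl2 with Ccl12 and H2-T23 with H2-T22, against a mean of 0.953 and a 95th percentile of 3 in 10000 random placements (permutation p = 0.243), so chromosome segments of different strain origin stay open here. The other comparisons had fewer pairs than the random mean, 2 against 2.88 in SOD1-G93A against SOD1-WT and 14 against 16.4 in SOD1-WT against nontransgenic glia. A window of 10 measured genes sees only close neighbours, so these counts cannot exclude longer segments in any comparison. Only 3 of the 31 genes had another kept probe, and 33.3% of those changed the same way by at least 50% as much (Fbln1, but not Ccl12 or H2-T22). In the other comparisons it was 6 of 9 (66.7%) and 10 of 19 (52.6%). Sequence variants under single probes stay open for these differences, as 3 genes are too few to decide, and so does a change brought by the mutant transgene, as untested.

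The 3 Y-linked genes on the array were brighter on all 3 SOD1-WT arrays than on all 6 others, a pattern for which male cells in the SOD1-WT cultures and few in the others were considered. Kdm5d had a mean log2 intensity of 6.95 in SOD1-WT against 4.15 in nontransgenic and 4.17 in SOD1-G93A glia, and was detected on the 3 SOD1-WT arrays alone. Eif2s3y was detected on 2 of them and Uty on none. Pups of different sex may have given the cultures, which the labels do not state, but this was proposed from the same arrays, so the value of 3 genes cannot test it. Sex and transgene cannot be separated in the comparisons with SOD1-WT glia, since no SOD1-WT array lacked Kdm5d and no other array had it.

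Other splits of the arrays were counted for each comparison. For the pairwise comparisons the 10 splits of 6 arrays are too few for a share under 0.05: 1 of 10 gave as many probes, the real one, with 1487, 2102 and 3539 against a highest other of 0 in each. For lists, 2 of 10 gave as many as the 5 in SOD1-G93A against nontransgenic glia (highest other 5), 1 of 10 as many as the 7 in SOD1-G93A against SOD1-WT (highest other 4) and 2 of 10 as many as the 4 in SOD1-WT against nontransgenic glia (highest other 5). For SOD1-G93A against the mean of both controls, 5 of 100 splits gave as many probes as the real 1083, with a highest other of 2187, and 5 of 100 as many as the 299 changed against both, with a highest other of 1135, so neither share is under 0.05 and chance is not excluded for either count. The 4 other splits put all 3 arrays of SOD1-WT (3 splits) or of nontransgenic glia (1 split) together, so they compare real groups and point to a structure of the samples. In the 93 other splits with a mixed group of 3, the highest counts were 416 probes and 0 changed against both. Mixed splits carry the group differences in their spread, so their low counts cannot exclude chance either. For the 8 lists of this contrast, 1 of 100 splits gave as many (highest other 7), a share under 0.05. The margin is a single list, since 7 other splits gave 7 lists, and the real count was 7 without SOD1-G93A replicate 2, 6 with detection on all arrays and 3 with an estimated correlation. The 8 lists also include the study's list, which was chosen on these samples and so favours the real split. Chance is therefore not excluded for this count, although its share is under 0.05.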

How the results depend on the processing

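No test here was chosen after the result was seen, except that Sod1 in 2 comparisons was counted with the named genes after its values were known. The counts of changed probes stayed within 1.5 times under every alternative other than leaving out an array, and the 346 named gene results kept direction and side of the threshold in 6373 cases, lost the call in 335, gained it in 2 and turned in 12. Dim probes limit the folds: with an offset of 50, 98 of 337 called gene results moved by over 1.5 times, against 6 with the authors' normalised values, since a larger offset shrinks changes near background. Leaving out nontransgenic replicate 1 so moved Trib3 in SOD1-WT against nontransgenic (-0.57 to -0.28), and leaving out SOD1-WT replicate 3 moved Glul in SOD1-G93A against SOD1-WT (0.68 to 0.35). With the replicate number as a paired block (replicate block) the probe counts were 1526, 2189, 3633, 1084 and 314, no list call changed, and 3 named genes lost theirs (Cdk1 and Slc1a2 in SOD1-G93A against nontransgenic, Dhcr7 in SOD1-G93A against SOD1-WT). Same-numbered arrays correlated at -0.021 to 0.153 (median 0.0763, against -0.040 for different numbers); 3 of 9 pairs were over 0.1, where all would be needed, and 2 of 9 arrays correlated best with their own number. The numbers were therefore not taken to pair the arrays.

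With an estimated correlation 0, 1, 1 and 3 lists shifted (from 5, 7, 4 and 8, in the order SOD1-G93A against nontransgenic, against SOD1-WT, SOD1-WT against nontransgenic, against the mean). The estimate was below the preset 0.01 for trophic factors (-0.0078), extracellular matrix and TGF-beta targets (-0.014), hindbrain and spinal identity (-0.016) and ependymal and choroid plexus (-0.039). For these lists, this argues against genes that vary together as the cause of the lost calls. Other lists that lost a call had estimates above the preset, as cell cycle (0.148), and there the cause was not tested. With fry, which does not compare a list with other genes, 17 shifted in SOD1-G93A against SOD1-WT and 18 in SOD1-WT against nontransgenic. In SOD1-G93A against nontransgenic, 3 lists shifted with no filter and 2 with detection on all arrays. Sod1 in SOD1-WT against nontransgenic was no longer past the threshold with median scaling (0.24, adjusted p = 0.2), cyclic loess (0.28, 0.0691), the authors' normalised values (0.28, 0.0937) and only the groups compared (0.33, 0.0602). Sod1 against the mean of both controls turned to -0.019, -0.010 and -0.0040 with the first 3 of these, and Ppbp in SOD1-G93A against SOD1-WT to -0.036 with array weights; none was past the threshold either way. The cause was not tested.

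Leaving out 1 array gave 645 to 1163 probes against the mean of both controls and 188 to 323 the same way against both, lowest without SOD1-G93A replicate 1; 3 to 5 lists in SOD1-G93A and 3 to 7 in SOD1-WT against nontransgenic. Log2 changes ranged from 0.27 to 0.44 for Sod1 in SOD1-WT against nontransgenic, -0.047 to 0.057 for Sod1 against the mean, -0.14 to 0.29 for Ppbp in SOD1-G93A against SOD1-WT, and -0.096 to 0.23 for Ccl5 and -0.081 to 0.016 for Ptgdr in SOD1-WT against nontransgenic. Fewer arrays give fewer degrees of freedom; the cause was not tested further.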

Other observations

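The test of motile cilia genes was chosen after a rise of a few ciliary genes in SOD1-WT glia had been seen, with a list written without those genes before its values were read. Genes of motile cilia, the beating appendages of ependymal cells, were higher in SOD1-WT glia. Of 39 measured genes 37 rose against nontransgenic glia and 0 fell, with a median log2 change of 1.30 (camera p = 1.58e-32; p = 0.000324 with an estimated correlation). Among them were Rsph4a, a radial spoke protein (2.34), Cfap52, a ciliary shaft protein (2.28), and Spag6l, a protein of the central pair (2.14). Foxj1, the transcription factor that turns on the programme of motile cilia, rose by 1.15 ± 0.12 (limma adjusted p = 6.63e-06, n = 3 per group); these 4 genes were picked after their values were seen. In SOD1-G93A against nontransgenic glia 17 rose and 0 fell, with a median of 0.36 (p = 0.00674 with an estimated correlation), and Foxj1 gave 0.26 (adjusted p = 0.235). In SOD1-G93A against SOD1-WT glia 0 rose and 34 fell, with a median of -1.05 (p = 0.000262 with an estimated correlation), and against the mean of both controls 1 rose and 19 fell (median -0.36, p = 0.00221 with an estimated correlation).

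A hypothesis is that the SOD1-WT cultures may hold more ciliated ependymal cells, with the mutant cultures in between. The list of ependymal and choroid plexus markers, fixed before the data were examined, did not pass in SOD1-WT against nontransgenic glia (4 of 7 up, 2 down, median log2 change 1.15, camera adjusted p = 0.0854, adjusted p = 0.283 with an estimated correlation). There it passed in 2 of 23 alternatives, detection on all arrays (camera adjusted p = 0.016) and fry (adjusted p = 6.99e-05). In SOD1-G93A against SOD1-WT glia the list did not pass either (2 up, 3 down, median -0.28, camera adjusted p = 0.308). The prediction was a shift of the list with both the preset and the estimated correlation, and the value of 0.000324 meets it. Ciliary genes had already been seen to rise on these arrays, so others of the same programme were likely to follow. The met prediction therefore adds little for a larger share of ependymal cells. A rise of ciliary genes within other cells of these cultures would give the same value and stays open, as does a difference in how the tissue was dissected.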
